A study of Homo sapiens with 8 samples.

How the data were processed

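Polyadenylated RNA was sequenced from 8 samples of HEK293 cells, 4 transfected with siRNA against NSUN2 and 4 with a scrambled control siRNA, 48 h after transfection. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was taken with oligo-dT beads and libraries were made with an Illumina TruSeq mRNA kit. Groups and replicate numbers came from the sample titles. The labels do not say whether the 4 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

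The authors deposited raw counts per Ensembl gene ID, 1 file per library, and these counts had not been normalized. Per the submitters' processing notes, TopHat2 (2.0.4) and DESeq were used and the build was GRCh37 (hg19). The counting program, its strand setting and the annotation release are not given in the sources used here. The column headers name skin where the labels name HEK293; this was left open. Each file closes with 5 entries that name no gene (reads with more than 1 alignment, ambiguous, outside genes, not aligned, of low quality). They held between 24.5% and 25.6% of the reads in the files and were left out of library sizes and tests; reads with more than 1 alignment were 13.4% to 15.0%. Genes that share sequence with a near copy, such as ribosomal protein genes, histones, HBA1 and vault RNAs, are therefore undercounted by an unknown amount. Without a stated use of strand, the counts of genes that overlap on opposite strands are uncertain.

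The files list 51172 gene IDs, of which 36452 (71.2%, with 99.0% of the counts) were matched by ID to a symbol in the reference tables. Gene types, transcripts and 3' untranslated regions (UTRs) came from GENCODE 29, matched by ID. That release is on GRCh38 and the files are on GRCh37, so no coordinates are given. Libraries held 48176207 to 55267069 counts on genes, and the biological coefficient of variation was 0.054. No pair of libraries was identical, and replicates of a group differed by 3.45 to 16.3 times the sampling noise (chi-square per degree of freedom), more than parts of 1 library would. Each was treated as 1 replicate, which does not show that the cultures were separate. Intervals that rest on counts alone would cover counting error only; the spread between libraries is used instead.

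The groups were compared with edgeR (4.0.16; quasi-likelihood fit with robust dispersion, TMM factors, prior count 2 for log2 CPM) in R (4.3.3), after filterByExpr with a minimum count of 10, which left 16947 genes. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg and calls used an adjusted p of 0.05. Standard errors are the log2 fold change divided by the square root of the quasi-likelihood F. CPM per group is given as mean ± SD. In all, 27 gene lists were fixed before the data were examined, and 26 with at least 3 tested members were tested with camera in limma (3.58.1; preset correlation of 0.01), beside camera with an estimated correlation and fry, whose p asks whether a list's genes move on balance one way and does not compare them with other genes. The genes named are NSUN2, then the 12 with the largest and the 12 with the smallest log2 fold change among called genes with a symbol, a mean of at least 5 CPM and groups that do not overlap. To these come all tested members of the m5C, vault and calcium channel lists and up to 4 members with the smallest p of every other list with a called member. The values of 2 genes within this rule are not reported here. Members named outside this rule, beside those so marked, were MDM2, VTRNA1-1, VTRNA1-2, CACNG7, KRT5 and KRT14, and they were chosen after their values were seen.

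Alternatives fixed before the data were examined were RLE and upper quartile factors, DESeq2 (1.42.0), limma-voom, no low-count filter, a mean of at least 5 CPM, a replicate block, 1 surrogate variable (sva 3.50.0), thinning to the smallest library, protein-coding genes only, each library left out in turn, a test against a 1.2-fold change (glmTreat) and an adjusted p of 0.01. Removing a trend in GC content and transcript length from each library was added after seeing the data.

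The tests were tried on simulated data made from the means and library sizes of these libraries. With 50 genes changed at each fold over the 16947 genes of the comparison, edgeR recovered 38 at 1.2-fold, 43 at 1.5-fold, 47 at 2-fold and 48 at 4-fold, and 14 of its calls (7.37%) were false, above the nominal share. Far fewer genes were changed than were called in the data, and genes of the lowest expression were not among them, so these shares may not carry over. Of 50 random gene lists, camera called 0. Those lists held unchanged genes, each drawn independently of the others. The 0 therefore does not cover lists whose genes correlate.

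For 3' UTR sites, each gene was represented by the 3' UTR of its GENCODE 29 transcript with the longest coding sequence, if at least 50 bases long. Each of 16190 heptamers found in at least 50 genes was examined across 12969 genes. The mean log2 fold change of genes with it was compared with that of genes without it. A quadratic fit of 3' UTR length and GC content was removed first, and the adjusted value of NSUN2 was then set to 0. Heptamer shifts given before adjusting include NSUN2. MicroRNA sites were the complements of seed bases 2 to 8 of 16 families that HEK293 cells are known to express and 14 of other tissues, listed before the test. In simulated data, a heptamer planted with a shift of 0.08 (log2) ranked first in 19 of 20 draws. That shift is larger than the 0.062 of the highest ranked heptamer in the data, and smaller shifts were not tried. These steps used Python (3.11.15) with numpy (2.4.6), pandas (2.3.3) and scipy (1.17.1); plots used matplotlib (3.10.9).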

Results

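The messenger RNA of HEK293 cells, a line derived from human embryonic kidney, was counted after the RNA methyltransferase NSUN2 was knocked down. NSUN2 places 5-methylcytosine (m5C) in transfer RNAs and in other RNAs, and the series concerns its methylation of vault RNAs, short non-coding RNAs of the vault particle, and their processing into small RNAs. In all, 4 libraries came from cells transfected with a small interfering RNA (siRNA) against NSUN2 and 4 from cells transfected with a scrambled control siRNA, harvested 48 h after transfection. The libraries held between 48176207 and 55267069 counts on genes, with a mean of 5.31e+07 ± 1.98e+06 (SD, n = 4) with NSUN2 siRNA and 4.96e+07 ± 1.06e+06 (SD, n = 4) with control siRNA. The 1 comparison of the design asks how the transcripts of these cells differ when NSUN2 is low.

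NSUN2 itself (ENSG00000037474), the targeted gene, fell from 177 ± 2.64 CPM (counts scaled to library size; SD, n = 4) in control libraries to 19.6 ± 0.358 CPM (SD, n = 4) in NSUN2 siRNA libraries, which is 11.1% of the control level. Each NSUN2 siRNA library held between 992 and 1072 counts of the gene, against 8598 to 9002 in each control library. The log2 fold change was −3.17 ± 0.03 (SE), with the smallest adjusted p of all tested genes, 1.88e-27 (edgeR quasi-likelihood test).

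**Figure D1:**
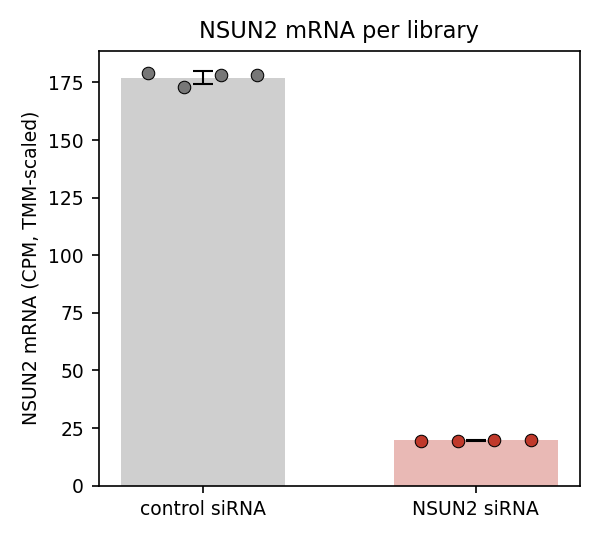
NSUN2 mRNA in CPM (y axis, from 0) in the 4 control siRNA and the 4 NSUN2 siRNA libraries. Points are libraries, bars are means and error bars are SD; the NSUN2 siRNA libraries lie between 19.2 and 20.03 CPM and the control libraries between 173 and 179 CPM.

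Among called genes with a symbol, a mean of at least 5 CPM and groups that do not overlap, the transcripts that rose most with NSUN2 siRNA were those of PRTG (protogenin, an immunoglobulin superfamily receptor of neural development), NR6A1 (an orphan nuclear receptor) and ZNF367 (a zinc finger transcription factor). PRTG (ENSG00000166450) rose from 26.9 ± 1.80 to 97.1 ± 3.33 CPM (SD, n = 4 each), a log2 fold change of 1.85 ± 0.04 (SE). NR6A1 and ZNF367 each rose by 1.38 on the log2 scale. The other 9 of the 12 largest rises, from 1.25 down to 0.97, were ENPP5, MIGA1, CYBRD1 and SLC40A1 (a plasma membrane ferric reductase and the iron exporter ferroportin), FYCO1 (an adaptor of autophagosome transport), ZBTB4, TMEM245, ATXN1 and CROT. The largest falls after NSUN2 within the same limits were those of STMN3, a stathmin that binds tubulin, at −1.92 ± 0.07, TMEM150A at −1.80 ± 0.11, ATP6V0C, a subunit of the proton pump of acidic organelles, at −1.59 ± 0.03, and SYP, the synaptic vesicle protein synaptophysin, at −1.47 ± 0.075 (log2 ± SE). ATP6V0C was the most abundant of these and went from 129 ± 3.38 CPM (SD, n = 4) in control libraries to a level 3.01-fold lower. The remaining falls, from −1.37 to −1.06, were KCNC1 (a voltage-gated potassium channel), SLC45A3, CCDC69, ZDHHC22, NOG (the BMP antagonist noggin), DMBX1 and PNMA2. For each of these 24 genes, the 4 values of one group lay apart from the 4 of the other, and their adjusted p-values from edgeR's quasi-likelihood test were 1.92e-08 or lower.

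**Figure D2:**
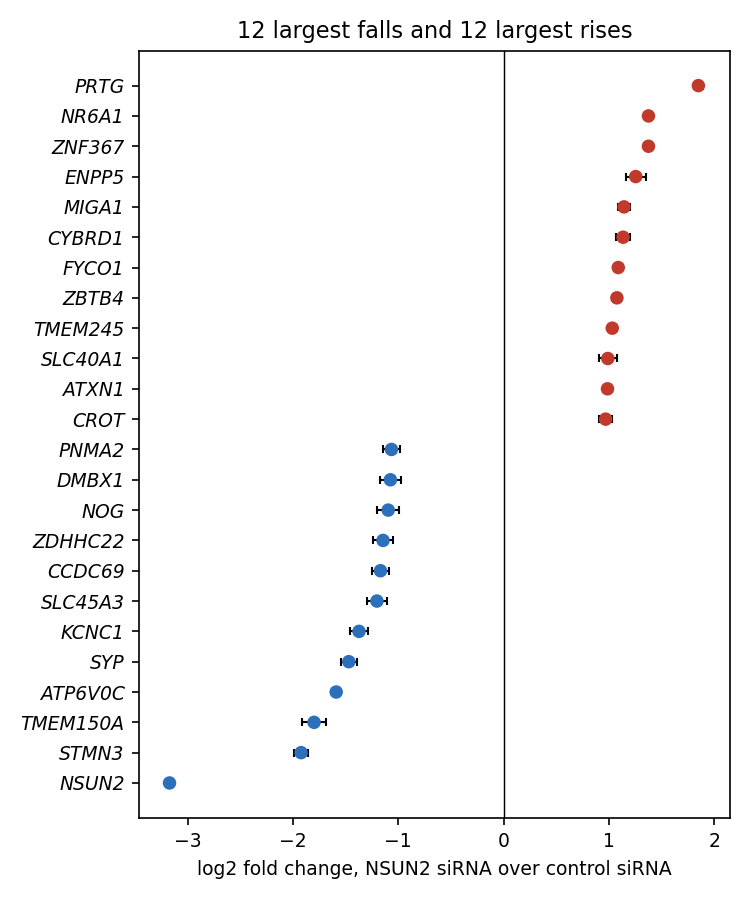
Log2 fold change of NSUN2 siRNA over control siRNA (x axis) for the 12 largest rises and the 12 largest falls among genes with a mean of at least 5 CPM. Points are estimates from 4 libraries per group and bars are standard errors; NSUN2 lies at −3.17 and PRTG at 1.85.

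Of 16947 genes tested, 5342 (31.5%) differed between the groups at an adjusted p below 0.05, 2774 of them higher and 2568 lower with NSUN2 siRNA. Most of the differences were small: the median absolute log2 fold change of the called genes was 0.225, 512 changed at least 1.5-fold and 119 at least 2-fold. Larger changes were mostly falls, with 92 genes lower and 27 higher by 2-fold or more, counted without an expression floor. With a mean of at least 5 CPM and groups that do not overlap, 2327 called genes were higher and 1747 lower, at any fold. The values of both groups did not overlap for 5177 genes (30.6%), against the 2.86% that chance gives for 4 against 4. The share of calls that were higher was 51.9% with trimmed mean of M-values (TMM) factors and 39.2% with upper quartile factors. A test against a 1.2-fold change called 729 genes.

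Of the 26 gene lists with at least 3 tested members, 4 moved beyond the other genes (camera, adjusted p below 0.05), and 3 of these calls held with an estimated correlation between genes. Genes of the unfolded protein response of the endoplasmic reticulum (ER) were higher with NSUN2 siRNA: 14 of 17 rose, 0 fell, and 15 rose adjusted over the list alone (camera adjusted p = 2.42e-06). The chaperone HSPA5 (BiP) rose from 640 CPM by 0.26 on the log2 scale, HYOU1 rose by 0.40, the co-chaperone DNAJB9 by 0.52 and the secreted factor MANF by 0.35. Genes of small RNA processing and silencing were higher too, with 11 of 16 that rose, 0 that fell and 12 that rose adjusted over the list alone (camera adjusted p = 1.04e-05). They included the silencing scaffolds TNRC6B (0.74 ± 0.03, log2 ± SE) and TNRC6A (0.57 ± 0.03), the microRNA-producing nuclease DICER1 (0.47 ± 0.03) and the Argonaute AGO2 (0.33 ± 0.04). Among p53 targets, 11 of 22 rose and 1 fell, 12 and 1 adjusted over the list alone (camera adjusted p = 0.000291). The antiproliferative gene BTG2 rose by 0.855, the death receptors TNFRSF10B and FAS by 0.57 and 0.67, and the cell cycle inhibitor CDKN1A by 0.47. MDM2, a p53 target that encodes the ligase of p53, had a log2 fold change of 0.011 ± 0.035 (SE) and did not pass the test. The 1 that fell was CCNG1 (−0.16), chosen here after its value was seen.

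The fourth list, genes of the ATF4 integrated stress response, was lower: 14 of 24 fell and 1 rose, 16 and 1 adjusted over the list alone (camera adjusted p = 4.74e-05, but adjusted p = 0.197 with an estimated correlation, so the call was lost). The glutathione-degrading enzyme CHAC1 was at −1.285 ± 0.11 (log2 ± SE), asparagine synthetase ASNS fell by 0.51, DDIT4 by 0.46 and the amino acid transporter SLC7A5 by 0.36. The 1 that rose was the lipoprotein receptor VLDLR (0.68), chosen after its value was seen. The calls of the ER, silencing and p53 lists held with an estimated correlation between genes (adjusted p = 0.0239, 0.0239 and 0.0359).

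**Figure D3:**
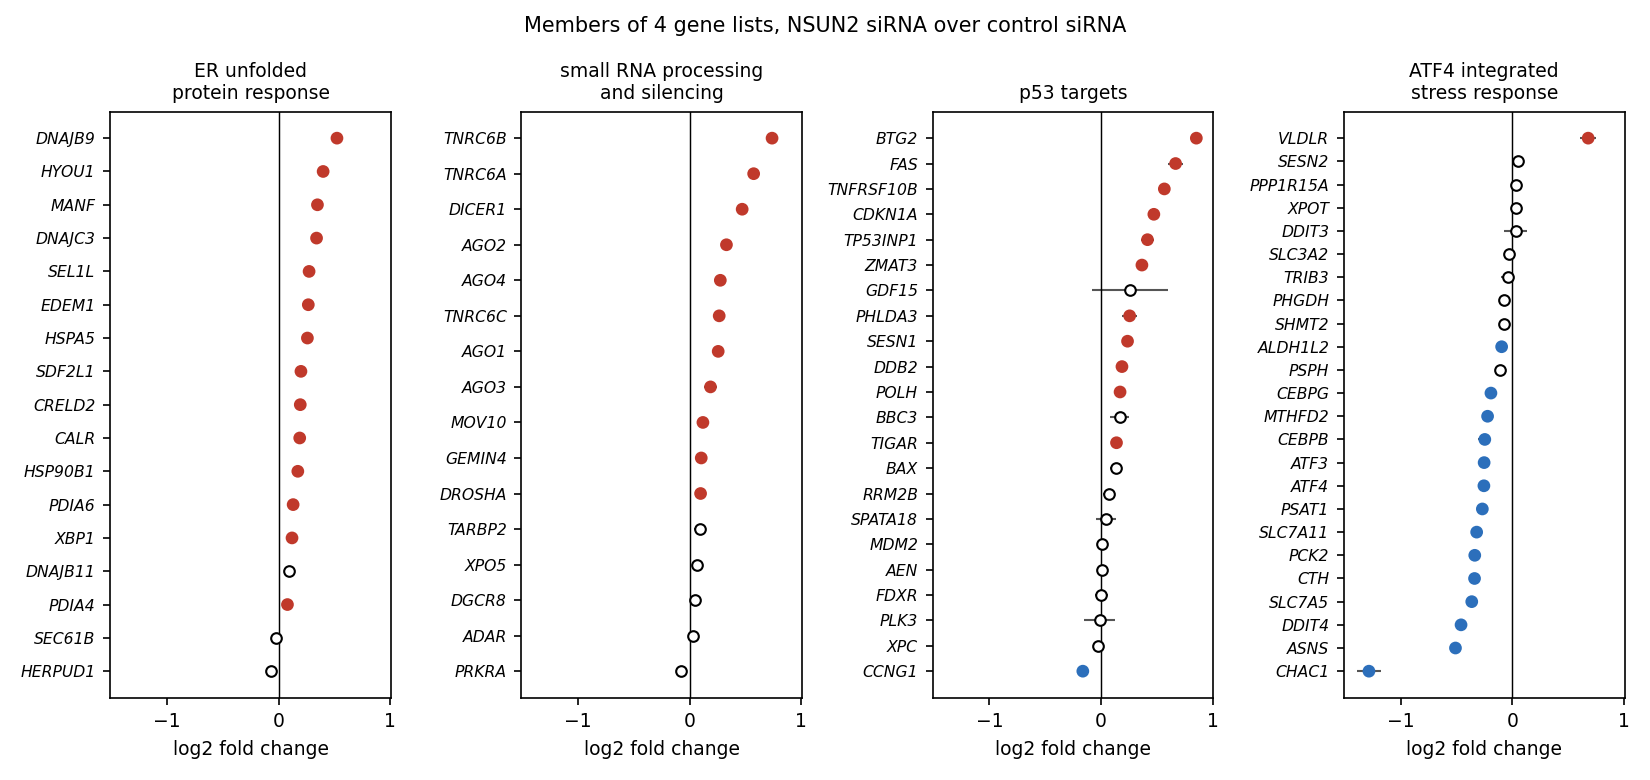
Log2 fold change of NSUN2 siRNA over control siRNA (x axes) for each tested member of 4 gene lists, from 4 libraries per group, with standard errors as bars. Filled points passed an adjusted p of 0.05 (red higher, blue lower) and open points did not; 14 of 17, 11 of 16 and 11 of 22 members rose in the first 3 lists and 14 of 24 fell in the ATF4 list.

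The other tested members of the m5C list changed by at most 0.26 on the log2 scale in either direction. Of 11 tested members, NSUN2 and the m5C-binding export factor ALYREF (−0.26 ± 0.03, log2 ± SE) fell, NSUN4 (0.19 ± 0.04) and NOP2 (0.13 ± 0.03) rose, and 7 did not pass; the counts were 2 and 2 adjusted over the list alone. NSUN3, NSUN5, NSUN6, TRDMT1, YBX1 and YTHDF2 lay between −0.02 and 0.08. DNMT1 was at −0.07 ± 0.03 (adjusted p = 0.0730, edgeR) and passed under 6 of 19 alternatives, 1 of them without control replicate 1 (adjusted p = 0.0309, edgeR), with adjusted p-values from 0.00962 to 0.247. The camera adjusted p of the list was 0.761. It was 5.69e-11 on DESeq2 statistics and ranged up to 0.975 over the alternatives; NSUN2 itself is a member, and the mean of the list (−0.27) had the opposite sign of its median (0.02).

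In the vault particle, the major vault protein MVP fell by 0.66 ± 0.16 (log2 ± SE), from 2.77 to 1.74 CPM (adjusted p = 0.00264, edgeR). PARP4 was higher by 0.11 ± 0.04 (adjusted p = 0.0292, edgeR), a call that was lost under 7 of 19 alternatives, over which the adjusted p ranged from 0.0170 to 0.149. It was lost without control replicate 4 (adjusted p = 0.113, edgeR) and without NSUN2 siRNA replicate 1, 2 or 4 (0.0728, 0.0563 and 0.0744). TEP1 was at −0.004 ± 0.050. Vault RNAs lack a poly(A) tail, and the libraries were made from poly(A)-selected RNA: VTRNA1-1 had at most 2 counts in any library, VTRNA1-2 at most 7, and VTRNA1-3 at most 81. VTRNA1-3 was at 1.06 ± 0.138 CPM (SD, n = 4) with control siRNA and 1.40 ± 0.113 CPM (SD, n = 4) with NSUN2 siRNA, which did not pass (adjusted p = 0.107, edgeR). The list had 1 rise, 1 fall and 2 members that did not pass, the same counts adjusted over the list alone, a median of 0.05 against a mean of −0.04, and a camera adjusted p of 0.761. The calcium channel gamma subunits were hardly expressed apart from CACNG8. It alone of 8 could be tested and did not change detectably, with a log2 fold change of −0.02 ± 0.05 (adjusted p = 0.759, edgeR). CACNG7 had at most 15 counts in any library.

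Genes of tRNA cleavage and maturation included 6 rises and 0 falls among 22 (6 and 0 adjusted over the list alone; camera adjusted p = 0.273), among them the ribonuclease inhibitor RNH1 (0.33). Of 20 cytosolic aminoacyl-tRNA synthetases, 7 fell and 3 rose, 9 and 3 adjusted over the list alone (camera adjusted p = 0.226); WARS1 fell by 0.22 and NARS1 by 0.19, and HARS1 rose by 0.20. In the interferon and double-stranded RNA list, 6 of 21 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.217). IFIH1, a sensor of double-stranded RNA, and IFI44L rose by 0.58 and 0.58 (0.583 and 0.585), IFIT1 fell by 0.67, and the large rise of IFIT2 started from 0.0848 CPM. That list passed without a low-count filter (0.0258), within a range up to 0.897 over the alternatives, and had 0.362 with an estimated correlation.

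Cell cycle genes went both ways. In G1/S, 2 of 21 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.761), with MCM5 at 0.19, E2F1 at −0.25, and a median (0.003) and mean (−0.014) of opposite sign. In G2/M, 7 of 24 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.286), with KIF23 at 0.52, MKI67 at 0.37 and BIRC5 at −0.17. Replication-dependent histones had 2 rises, H2BC12 (0.30) and H1-2 (0.32), among 12, the same adjusted over the list alone (camera adjusted p = 0.761); their mRNAs lack poly(A) tails, and the median (0.09) and mean (−0.02) of the list differed in sign. H1-4 had its largest log2 fold change, −0.80 ± 0.30 (SE), and did not pass (adjusted p = 0.0752, edgeR). It passed under 5 of 18 alternatives, among them without NSUN2 siRNA replicate 1 (adjusted p = 0.00841, edgeR) or 3 (0.00858), with a range from 3.89e-06 to 0.159. Among 25 genes of ribosome biogenesis, 6 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.761). Nucleophosmin NPM1, at 2846 CPM in control libraries, fell by 0.36, and HEATR1 rose by 0.30.

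Of 50 cytosolic ribosomal protein genes, 12 fell and 0 rose, the same adjusted over the list alone, with RPL37 and RPS20 lower by 0.16 each (−0.158 and −0.163). Their camera adjusted p of 0.0564 fell below 0.05 under 10 of 19 alternatives and ranged from 0.00196 to 0.863, but with an estimated correlation between genes (0.280) it was 0.862. Those below 0.05 included leaving out control replicate 1 (0.00196), control replicate 3 (0.0469) or NSUN2 siRNA replicate 1 (0.0341). Among 36 nuclear-encoded genes of oxidative phosphorylation, 3 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.666), with UQCRC2 at −0.20 and SDHC at −0.21. None of the 13 mRNAs of mitochondrial DNA passed edgeR's test, 0 adjusted over the list alone as well and 0 at an unadjusted p below 0.05, and their camera adjusted p was 0.935.

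Metabolic and stress genes outside the 4 called lists changed as follows. In the cholesterol list, 7 of 22 rose and 4 fell, 8 and 4 adjusted over the list alone (camera adjusted p = 0.273), with INSIG1 at 0.37 and the epoxidase SQLE at −0.22. In the hypoxia and glycolysis list, 9 of 20 fell and 1 rose, 9 and 2 adjusted over the list alone, with NDRG1 at −0.38, PFKFB3 at −0.29 (−0.285) and VEGFA at −0.23. The camera adjusted p was 0.0662 and fell below 0.05 under 6 of 19 alternatives, without control replicate 3 (0.0469) among them, with a range from 0.0185 to 0.149; with an estimated correlation it was 0.199. Of 17 heat shock genes, 4 rose and 4 fell, 5 and 5 adjusted over the list alone (camera adjusted p = 0.935), with DNAJB1 at 0.24 and CHORDC1 at −0.27. Of 19 immediate early genes, 5 rose and 5 fell, 6 and 5 adjusted over the list alone (camera adjusted p = 0.958), with JUN at 0.26, MCL1 at 0.27 and ATF3 at −0.25. The median and mean of that list were −0.05 and −0.07 although camera's direction was upward.

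Matrix genes and lineage markers moved in both directions. In the extracellular matrix list, 8 of 18 rose and 2 fell, 8 and 3 adjusted over the list alone (camera adjusted p = 0.0914; 0.0363 on DESeq2 statistics, up to 0.255 over the alternatives, 0.205 with an estimated correlation), with LAMC1 at 0.47 and SMAD7 at 0.49. Among 13 neuronal genes, 5 fell and 2 rose, the same adjusted over the list alone, with the neurofilament gene NEFM at −0.59 and MAPT, which encodes tau, at −0.33. Their camera adjusted p of 0.0678 was 0.0341 without NSUN2 siRNA replicate 1 and ranged up to 0.405; with an estimated correlation it was 0.202. Of 8 kidney genes, the nephron progenitor factor SIX2 (−0.64) and PODXL (−0.32) fell and LRP2 (0.26) rose, the same adjusted over the list alone (camera adjusted p = 0.935; median 0.09, mean −0.07 (−0.065 in full)). Markers of other cell types showed no common direction. Of 6 fibroblast markers, COL3A1 rose (0.42; camera adjusted p = 0.761), of 5 keratinocyte-type markers DSC3 rose (0.21; camera adjusted p = 0.935), and of 6 haematopoietic markers CORO1A fell (−0.47; camera adjusted p = 0.368), with the same counts adjusted over each list alone. The keratinocyte-type list had a median of −0.09 and a mean of −0.05 although camera's direction was upward. KRT14 had 0 counts in every library and KRT5 at most 1. Of 12 fibroblast and 13 keratinocyte-type markers in the files, only 6 and 5 passed the count filter. Among these, DSC3 was at 59.2 CPM, CDH3 at 5.81 CPM, COL1A1 at 33.9 CPM and COL3A1 at 10.8 CPM in control libraries.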

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

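In groups of 4 libraries, a library was singled out where the ratio of its gap to the nearest of the others over the range of the group passed the critical value of Dixon's test. No test in this part was chosen only after its result was seen, but TTAGGAT was scored because of its rank among heptamers. Chance does this in about 5% of groups, and it happened in 20 of 284 (7.04%), over named genes, library measures and 3' UTR site scores. No library stood out in most of them: NSUN2 siRNA replicates 3 and 4 and control replicate 2 each accounted for 4.

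NSUN2 in control replicate 2 was 173 CPM against 178 to 179 in the other controls (gap ratio 0.874), a distance that is small beside the knockdown. Among the largest rises and falls, ATXN1 was low (0.843) and CROT high (0.857) in NSUN2 siRNA replicate 1, and ZDHHC22 was low in control replicate 1 (0.902). The low VTRNA1-3 value of control replicate 4 (0.852 CPM against 1.10 to 1.15 in the others, ratio 0.845) widens the difference between the groups for that vault RNA, which did not pass the test. HBA1 was high in the same library (1.33 CPM, ratio 0.907).

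In list genes of NSUN2 siRNA libraries, replicate 3 was low for HEATR1 (0.845) and SIX2 (0.858) and high for SDHC (0.848) and MSMO1 (0.881), and replicate 4 was low for RPL5 (0.884) and high for INSIG1 (0.910), HSPB1 (0.868) and INA (0.837). In control libraries, replicate 1 was low for SLC7A5 (0.830), replicate 2 was high for SRM (0.870) and DUSP1 (0.836), and replicate 3 was high for NDRG1 (0.830). Of the site scores, that of microRNA families of other tissues was low in control replicate 4 (0.895) and that of TTAGGAT high in control replicate 2 (0.898).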

How the results depend on the processing

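The removal of a GC and length trend was the 1 alternative chosen after the data were seen. The count of 5342 called genes stayed within 1.5 times under the 10 other planned fits of all libraries (5036 to 6162), with 1 library left out (4626 to 5374, 8 fits), at an adjusted p of 0.01 (3822) and with the added GC and length trend removed (5602). Against a 1.2-fold change, 729 genes passed, 387 higher and 342 lower, by the construction of a test that removes small changes. Upper quartile factors shifted the median log2 fold change by −0.03, called 5534 genes, 4738 of them called in the same direction with TMM, and put 39.2% of calls higher against 51.9%. NSUN2 ranged from −3.21 to −3.16 (log2) over 19 alternatives. The count of called lists was 4; it was 8 on DESeq2 statistics and 7 without a low-count filter (the cause was not tested), and 15 with fry, which does not compare a list with other genes. With an estimated correlation it was 3. Over the alternatives, 2406 of 2431 values of 129 named genes kept direction and side of the threshold, 11 lost a call (5 genes, PARP4 and 4 with the GC and length trend removed: RPL5, RPL38, NDUFB3 and ATP5F1C), 14 gained one and 0 reversed. Of 541 list values, 509 kept theirs, 1 lost a call, 31 gained one and 0 reversed.

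The labels number the replicates of both groups alike. Same-numbered samples did not deviate together (correlations of 0.03, −0.12, 0.03 and −0.18), and 0 of the 8 samples correlated best with its own number. With the replicate number as a block, 5113 genes passed, 5007 of them the same genes in the same direction, and 4 lists. Genes that failed the count filter, such as VTRNA1-1, CACNG7 and 7 members of the interferon list, could not be tested.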

Other observations

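In this part, the search by shared symbol prefix, the count of miR-17 sites in the largest rises and the removal of a GC and length trend were tests chosen only after the result was seen. The tests of heptamers against NSUN2's own transcripts and the lower genes were set after the ranking of heptamers was known, and the jackknife SE of the silencing list was added after its percentage was seen.

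Messenger RNAs with 3' UTR sites for microRNA families listed as expressed in HEK293 cells were on average higher with NSUN2 siRNA, for some families far more than for others. MicroRNA levels were not measured. Of 16190 heptamers, the highest ranked was GCACTTT, the site of miR-17, miR-20, miR-93 and miR-106: the 2842 genes with it were higher by 0.062 on the log2 scale than those without it (z = 10.84). TTTGCAC (miR-19) ranked 2, TTGCACT (miR-130 and miR-301) 6, GTGCAAT (miR-25 and miR-92) 7 and TGCTGCT (miR-15 and miR-16) 12. In all, 10 heptamers lay above 5.30, the highest z in 100 random reassignments of fold changes to genes. Sites of let-7 (rank 1970), miR-10 (1897), miR-21 (1417) and miR-27 (4015) were not in the top 161. The site of miR-124, listed as a family of another tissue, ranked 39.

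Of the 12 largest rises, 10 have a miR-17 family site: ZNF367, ENPP5, MIGA1, CYBRD1, FYCO1, ZBTB4, TMEM245, SLC40A1, ATXN1 and CROT. PRTG and NR6A1, which are among the 3 largest, have none, and both have a let-7 site. Random sets of genes of like 3' UTR length held 5.36 on average. Site and genes were both picked by these fold changes, so the count describes the genes and is no separate test. Of 11 of the largest falls, 2 have one (2.68 on average in random sets). Genes called higher had sites for a mean of 3.03 of the 16 families, genes called lower for 2.13 and genes not called for 1.99, without adjusting for 3' UTR length.

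For the rise of mRNAs with microRNA sites, 3 explanations were tested. Length and GC content of the 3' UTR do not account for it: the mean shift of the 16 families was 0.0285 after adjusting and 0.0432 before. The adjusted shift exceeded that of 14 families of other tissues (−0.0011, permutation p = 3e-05). The permutation takes families as independent, but some expressed ones have sites that share bases, so this p may overstate the evidence. A seed of the control siRNA that is active in the control samples only would raise sites of at most its 2 strands, if it is a single duplex. Of the families in the top 1%, 9 have sites that share no run of 5 bases, which met the rule set beforehand against such a seed. That count cannot decide, as most of these families, such as miR-181 (z = 2.66), lie below 5.30, the highest z of the random reassignments. Among them, only GCACTTT, TTTGCAC, TTGCACT and GTGCAAT lie above it. GCACTTT, TTTGCAC and TTGCACT overlap and all hold GCAC, so they may be a single signal. A seed of the control siRNA therefore stays open. Release of endogenous microRNA targets would give a difference such as the 0.0296 between expressed and other families. Scored per library, the shift of the expressed families separated all 4 NSUN2 siRNA libraries (0.0142 ± 0.0012, SD, n = 4) from the 4 controls (−0.0142 ± 0.0007). The exact permutation p was 0.0286, the smallest that 8 libraries can give. These scores restate the mean shift library by library, so they are no separate support for a release. Whether such a release follows from low NSUN2 or from differing competition of the 2 siRNAs for Argonaute stays open, since both go with the group.

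Among heptamers of lower mRNAs, TAGGATA stood out, carried by 894 genes that were lower by 0.055 on the log2 scale after adjusting for 3' UTR length and GC content and by 0.031 before (adjusted z = −6.06; lowest in the reassignments −5.16), followed by TCGTCTT (z = −5.00) and TTAGGAT (z = −4.54; shift of −0.0342 after and −0.0113 before). A seed of the NSUN2 siRNA is consistent with the −6.06, as TAGGATA is no site of a listed expressed family. A guide strand of the NSUN2 siRNA, which pairs along its whole length with the NSUN2 mRNA, needs the heptamer in that mRNA, and 4 of 9 GENCODE 29 transcripts of NSUN2 hold it; these transcripts hold 26.8% as many different heptamers as were tested, so a match by chance is not rare. The match is not particular to TAGGATA: TCGTCTT occurs in 6 of the 9 transcripts, and 6 of the 10 strongest downward heptamers occur in at least 1. The siRNA sequence is not given in the sources used here, so an off-target seed stays a hypothesis.

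Of 35 splits of the 8 samples into 4 and 4, only 1, the real split, called as many as 5342 genes. The highest of the others called 0. Every other split mixes the real groups, so the group difference enters its within-group spread and few calls were likely in advance. If the 4 samples of a group share a culture, the splits cannot tell a chance difference between cultures from an effect of the siRNA. A GC content and length trend between libraries does not account for the calls. Once it was removed, 89.3% of called genes with a value were called in the same direction. Of 2239 lower genes, 17.6% carry TAGGATA or TTAGGAT, against 13.9% of 2608 higher genes and 11.9% of genes not called. Of 62 genes lower by 2-fold or more, 12.9% carry them. This argues against matches to these heptamers as the main cause of the lower calls. Other seeds of the NSUN2 siRNA were not counted, among them TCGTCTT. Since the siRNA sequence is not given, seed matches in general are not excluded. Low NSUN2 and other effects of this siRNA cannot be separated by this design of 1 siRNA, and neither was tested against the other.

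Vault-derived small RNAs that act like microRNAs would leave a mark on mRNAs with a match to a heptamer of vault RNA 1-1. Of 93 such heptamers, the strongest reached an absolute z of 3.47 with a shift of 0.0193 (log2). A share of 0.254 of 10000 random draws of as many heptamers held one as strong, so no such mark was detected at 48 h. The simulated data held a planted shift of 0.08, so the power to find a mark this small was not tried. The rise of the small RNA processing and silencing list may come in part from microRNA sites in the 3' UTRs of its own members. These have sites for a mean of 5.88 families against 2.22 over all genes. Adjusting for sites (present or absent per family), length and GC content left 76.1% (jackknife SE 6.9) of the mean, and 14 of 16 members kept a rise. For these members, this argues against such sites as the source of most of the rise. Whether they give a smaller part was too close to the 75% set beforehand to decide. Of 70 gene families that share a symbol prefix, 0 passed camera at an adjusted p of 0.05, with a preset or an estimated correlation, and 9 had an unadjusted p below 0.05.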
